A study of Mus musculus with 8 samples.

How the data were processed

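RNA from 8 mouse ES cell samples was measured on single-colour Illumina BeadChips, 1 array per sample. Per the labels, total RNA was taken with the mirVana kit, amplified to biotin-labelled cRNA from 0.55 ug with the TotalPrep kit and read with BeadStudio 3.1.3. Groups and replicate numbers were taken from the labels. They gave 3 androgenetic, 2 parthenogenetic and 3 fertilized arrays, and all 8 were used. The number of independent lines, the slide of each array and the number of X chromosomes per cell in androgenetic and fertilized lines are not given there.

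The deposited table of non-normalized values holds, for 25697 probes, a linear intensity per array, which was positive throughout and not scaled between arrays. Beside each intensity the authors deposited a detection p-value, in steps of 1/798. A separate deposited table holds log2 values for 12891 probes. Taking log2 of the signals of the probes with a detection p under 0.05 on at least 4 arrays and quantile normalizing them reproduced that table to within 0.000742, and no background subtraction was visible in it. The tests used the non-normalized table. Gene names came from the probe annotation of the array given with the study, which lists 12145 of those 12891 probes with 1 gene each. Chromosomes came from RefSeq genes of mouse assembly GRCm38.p6.

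Signals were corrected and normalized with neqc in limma 3.58.1 under R 4.3.3, with background estimated from the detection p-values, quantile normalization and an offset of 16, and analysed on the log2 scale. The offset compresses the fold changes of dim genes. Probes with a detection p under 0.01 on at least 2 of 8 arrays were kept, 12300 in all. Of these, 11262 had a gene name and 1038 did not. Names cover probes of the authors' table alone, so a gene with a detection p under 0.05 on 3 or fewer arrays has no name here and can be missing. A gene detected only on the 3 androgenetic arrays can be lost this way, whereas this rule does not drop a gene undetected only there. Of the 1038 probes, 347 were outside that table, and the others lacked an entry in the annotation. The 8221 named genes were each represented by the probe with the highest mean over all arrays, a choice that 2176 genes with several probes needed. Opposite calls by probes of 1 gene occurred for 67, 21 and 43 genes in the 3 comparisons. No kept named probe measured H19, Meg3, Xist or Ddx3y.

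Median signals per array ran from 127 to 167, and 41.3% to 43.5% of probes were detected. The median SD within groups was 0.127 on the log2 scale. One linear model with a mean per group was fitted to all 8 arrays (5 residual degrees of freedom), so that the 2 parthenogenetic arrays shared the estimate of spread. Moderated two-sided tests (eBayes, prior degrees of freedom 3.51) were made for androgenetic against fertilized, parthenogenetic against fertilized and androgenetic against parthenogenetic cells, with Benjamini-Hochberg adjustment over kept probes and a threshold of 0.05. A fold against a group in which no array detected the gene is given as a lower bound, computed against the signal at which detection begins on those arrays, and none is given where some arrays of a group did not detect it. The 2-fold counts use fitted values and were 2004, 361 and 1954 with undetected genes at their bound. Replicate numbers did not pair the groups, as correlations of residuals between arrays of the same number lay between -0.090 and 0.067.

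Before the data were examined, 20 gene lists were fixed, along with the rule for named genes, the main tests and alternatives. Tests and alternatives chosen only after the result was seen are named as such below. Named genes were the 6 largest increases and 6 largest decreases per comparison among genes past the threshold whose arrays did not overlap, up to 4 members of each imprinted list and up to 2 of each other list, and 14 genes named in advance, of which those with a kept probe are given. The lists were paternally and maternally expressed imprinted genes, Y-linked genes, naive pluripotency, primed epiblast, primitive and extraembryonic endoderm, trophectoderm, primitive streak and mesoderm, neural genes, embryonic fibroblast markers, genes of the 2-cell-like state, germline genes repressed by promoter methylation, DNA methylation machinery, MAPK response, p53 targets, glycolysis and hypoxia, cholesterol synthesis, cell cycle, interferon-stimulated genes, and insulin-like growth factor and growth control. The 19 lists with at least 3 measured members were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over lists and comparisons, and again with an estimated correlation and with fry. Chromosomes were tested with camera in the same way, at the preset and at an estimated correlation, and not with fry. Overlap of the comparisons against fertilized cells was set beside counts for independent lists and beside 50 simulations of unchanged groups sharing the fertilized arrays.

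The model fit and its calls were tested on simulated log2 values with the same arrays, probes and spread, in which 67, 67 and 66 of 8221 genes had a known change of 1.5-fold, 2-fold and 4-fold. Background correction, normalization, the probe filter and probe choice were not simulated. Far fewer genes changed there than were called in the real data. Of genes changed 1.5-fold, 85.1%, 76.1% and 61.2% were called in the 3 comparisons. Of those changed 2-fold, 100%, 100% and 98.5% were called, and all changed 4-fold were, with 5, 12 and 2 false calls. Alternatives covered background correction, scaling, the authors' values, probe filters, the variance model, array weights, a replicate block, probe choice, fits of 2 groups, each array left out, division of the shared fertilized arrays, and thresholds. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.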

Results

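Gene expression was measured in mouse embryonic stem (ES) cells of 3 kinds. Androgenetic cells carry only paternal genomes, parthenogenetic cells only maternal genomes, and fertilized cells 1 genome from each parent. The lines came from blastocysts of the strain cross B6129F1. Androgenetic and fertilized cells were labelled female and male, with X and Y chromosomes, and parthenogenetic cells female. RNA was hybridised to 8 single-colour Illumina BeadChips. There were 3 androgenetic and 3 fertilized arrays, from passages 6, 7 and 8, and 2 parthenogenetic arrays, from passages 6 and 7. The labels do not say that the passages were separate lines, so p-values measure the spread between passages.

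Per array, 10623 to 11174 probes were detected above negative controls. A total of 12300 probes were kept, and those with a gene name represented 8221 genes. Arrays of the same kind resembled each other closely. Across kept probes the correlation was at least 0.997 within androgenetic, 0.996 within parthenogenetic and at least 0.985 within fertilized arrays, as a description across probes, which are not independent replicates. Parthenogenetic and fertilized arrays correlated at 0.961 to 0.967. Androgenetic arrays correlated with either at 0.861 to 0.868. The leading principal component, 81.8% of the variance, separated androgenetic arrays from the rest, and the next, 12.9%, separated parthenogenetic from fertilized arrays.

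Androgenetic cells were compared with fertilized cells to ask how expression differs when both genomes are paternal. Genes known to be expressed from the paternal allele were higher in androgenetic cells. Igf2, a fetal growth factor, was 3.91-fold higher (log2 fold change 1.97 ± 0.069 SE, adjusted p = 3.40e-08), at a level of 15.05 ± 0.012 against 13.08 ± 0.054 (log2 signal, SD, n = 3 each). Nnat was 10.9-fold, Peg10 7.78-fold, Mest 4.75-fold and Peg3, a zinc finger gene, 4.17-fold higher, with log2 changes of 3.44 ± 0.11, 2.96 ± 0.086, 2.25 ± 0.14 and 2.06 ± 0.17 (SE). Snrpn was nearly level, at 0.23 ± 0.071 (SE, adjusted p = 0.0162). Of 14 measured paternally expressed genes, 13 rose and 1 fell, with a median log2 change of 1.38 (camera adjusted p = 0.000330; adjusted p = 0.102 with an estimated correlation). Markers of embryonic fibroblasts were also higher in this comparison, 11 of 13 (median 2.20, camera adjusted p = 0.000330; adjusted p = 0.102 with an estimated correlation).

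Genes of the maternally expressed list were divided, and imprinting of each member in these cells was not measured. Grb10, an adaptor that restrains insulin signalling, was 76.1-fold lower (log2 fold change -6.25 ± 0.10 SE, adjusted p = 1.46e-09). Its androgenetic log2 signals of 6.70 to 6.83 lay just above the levels at which detection begins there, 6.63 to 6.73. The size of that fold therefore depends on the background and offset. Cdkn1c, an inhibitor of cyclin-dependent kinases, was 8.91-fold lower and Igf2r, the receptor that clears IGF2, 3.91-fold lower, with log2 changes of -3.16 ± 0.081 and -1.97 ± 0.080 (SE). Slc22a18 and Cobl were not detected on any androgenetic array and were at least 3.04-fold and at least 6.93-fold lower. Pon2, a member of the same list, was 9.76-fold higher. In all, 11 of 18 measured maternally expressed genes fell and 5 rose, and the list did not pass its test (median -0.60, or -0.35 with undetected genes at their bound; camera adjusted p = 0.142).

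**Figure D1:**
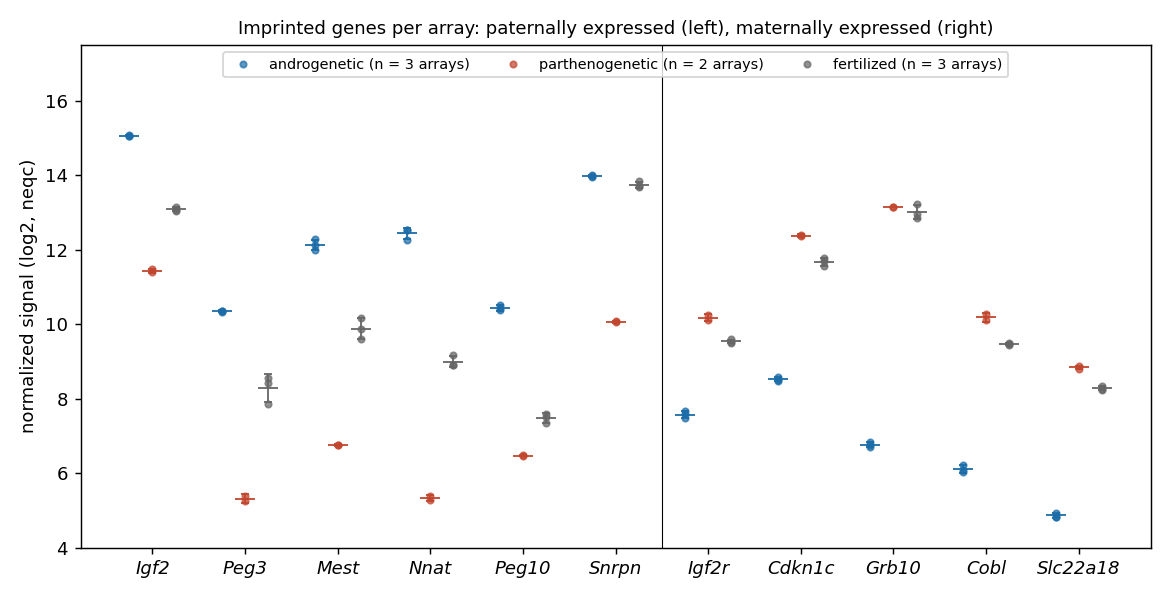
Normalized signal (log2 scale, y axis) of 6 paternally and 5 maternally expressed imprinted genes on each array. Points are arrays, horizontal marks group means and error bars SD over 3 androgenetic, 2 parthenogenetic and 3 fertilized arrays. Igf2 had means of 15.05, 11.43 and 13.08 in that order.

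Genes of the naive pluripotent state were lower in androgenetic than in fertilized cells. The core pluripotency factors Pou5f1, Sox2 and Nanog were 4.77-fold, 7.01-fold and 4.26-fold lower (log2 changes -2.25 ± 0.093, -2.81 ± 0.093 and -2.09 ± 0.13 SE). Fgf4, a growth factor made by ES cells, was at least 13.8-fold lower and Pecam1 at least 8.79-fold lower, and neither was detected on androgenetic arrays. Of 21 measured list members 18 fell and 2 rose (median -2.09, camera adjusted p = 2.48e-05; adjusted p = 0.0956 with an estimated correlation). Trophectoderm genes went the other way, with 10 of 12 higher and 1 lower (median 1.67, camera adjusted p = 0.000482; adjusted p = 0.102 with an estimated correlation). Eomes was at least 4.94-fold higher, and Gata2, above background on 1 of 3 fertilized arrays, also rose (adjusted p = 5.99e-08). All 7 measured neural genes rose, among them Gap43 (18.5-fold) and Nefm (at least 3.14-fold; list median 1.15, camera adjusted p = 0.000737; adjusted p = 0.102 with an estimated correlation).

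Markers of embryonic fibroblasts, a common feeder cell, moved with these groups. A total of 11 of 13 rose and 1 fell (median 2.20, or 1.52 with undetected genes at their bound; camera adjusted p = 0.000330; adjusted p = 0.102 with an estimated correlation). Col5a1 was 9.78-fold higher and Col1a1 at least 3.15-fold higher, at a mean log2 signal of 8.35 ± 0.17 (SD) in androgenetic cells. The primitive streak and mesoderm list, with 6 of 9 genes higher, did not pass its test (camera adjusted p = 0.0676), although Msx1 was at least 16.4-fold and Gsc at least 6.63-fold higher. Among primitive endoderm genes 7 rose and 4 fell of 14 (camera adjusted p = 0.402). Foxq1 was 7.37-fold higher and Amn 6.02-fold lower. Among primed epiblast genes 4 rose and 3 fell of 9. Otx2, which marks primed cells, was 21.4-fold lower and Sall2 at least 2.65-fold higher. That list had a median of 0.24, a mean of -0.22 and no call (camera adjusted p = 0.772).

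p53 target genes were higher in androgenetic cells, with 14 of 17 up and 1 down (median 0.93, camera adjusted p = 0.000525; adjusted p = 0.102 with an estimated correlation). Plk2 was 7.89-fold higher and Fas, a death receptor, at least 6.71-fold higher. Glycolysis and hypoxia response genes were lower, with 17 of 20 down and 2 up (median -1.34, or -1.30 with undetected genes at their bound; camera adjusted p = 0.000330; adjusted p = 0.211 with an estimated correlation). Pdk1, a kinase that inhibits pyruvate dehydrogenase, fell by 3.32 ± 0.085 and the oxygen sensor Egln3 fell by 3.26 ± 0.10 (log2, SE). Of 22 cell cycle genes 18 fell and 3 rose (median -0.91, camera adjusted p = 0.00307; adjusted p = 0.152 with an estimated correlation). Plk1, a mitotic kinase, was 3.33-fold lower, whereas Ccnd2, a cyclin of the start of the cycle, was 4.70-fold higher. Germline genes that promoter methylation silences in somatic cells also fell, in 11 of 12 cases (median -1.85, or -1.15 with undetected genes at their bound; camera adjusted p = 0.000330; adjusted p = 0.102 with an estimated correlation). Tex11 was at least 2.43-fold and Taf7l at least 2.37-fold lower. Beside these shifts, fibroblast markers were higher by a median of 2.20.

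The remaining lists did not pass their tests. Of 9 DNA methylation genes 6 fell and 2 rose (camera adjusted p = 0.107), with Dnmt3l, a cofactor of de novo methylation, 17.3-fold and Dppa3 3.98-fold lower. MAPK response genes were split 5 up and 5 down of 12 (camera adjusted p = 0.769), Dusp4 being 2.93-fold higher and Etv5 3.40-fold lower. Interferon-stimulated genes were split 5 up and 7 down of 14, with a median of -0.36, a mean of 0.062 and a camera adjusted p of 0.920. B2m was 5.13-fold and Isg15 4.02-fold higher. Growth control genes were split 8 up and 6 down of 14 (camera adjusted p = 0.430). Cholesterol synthesis genes were split 7 up and 3 down of 16 (camera adjusted p = 0.175), Hsd17b7 being 3.99-fold and Msmo1 3.02-fold higher. Of 4 genes of the 2-cell-like state 1 rose and 2 fell (camera adjusted p = 0.518), Zscan4c being at least 3.12-fold lower and Tcstv3 at least 1.90-fold higher. Neither of the 2 measured Y-linked genes passed the test, with Eif2s3y at -0.099 ± 0.12 and Uty at -0.24 ± 0.14 (log2, SE).

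Ranked by fitted values and not by bounds, the largest increases outside the lists were in Sp5, a target of WNT signalling (at least 66.6-fold), Gbp2b, an interferon-induced GTPase (at least 26.3-fold), the carbonic anhydrase Car2 (27.5-fold), Nipal2 (at least 10.7-fold), Wnt6 (at least 20.3-fold) and Edn1 (adjusted p = 1.89e-09, above background on 2 of 3 fertilized arrays). Ranked in the same way, the largest decreases beside Grb10 and Fgf4 were in Aire (at least 25.2-fold), Gpx2 (at least 34.4-fold), Gstp2 (at least 40.7-fold) and Pdzk1 (at least 14.6-fold). Overall counts were large. At an adjusted p under 0.05 (limma), 6140 of 8221 genes differed, 2908 higher and 3232 lower, and 2321 of them by at least 2-fold, 1084 higher and 1237 lower. The 1038 kept probes without a name leaned the other way, with 349 higher and 129 lower by at least 2-fold. The balance among named genes is therefore not that of all probes. The counts adjusted over the list alone were the same as those over all genes for each of the 20 lists. When only probes detected on all 8 arrays were used, 1507 genes passed the 2-fold count, and the medians of fibroblast markers and maternally expressed genes were 1.06 and -0.33. With the authors' values the median of germline genes was -1.15.

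**Figure D2:**
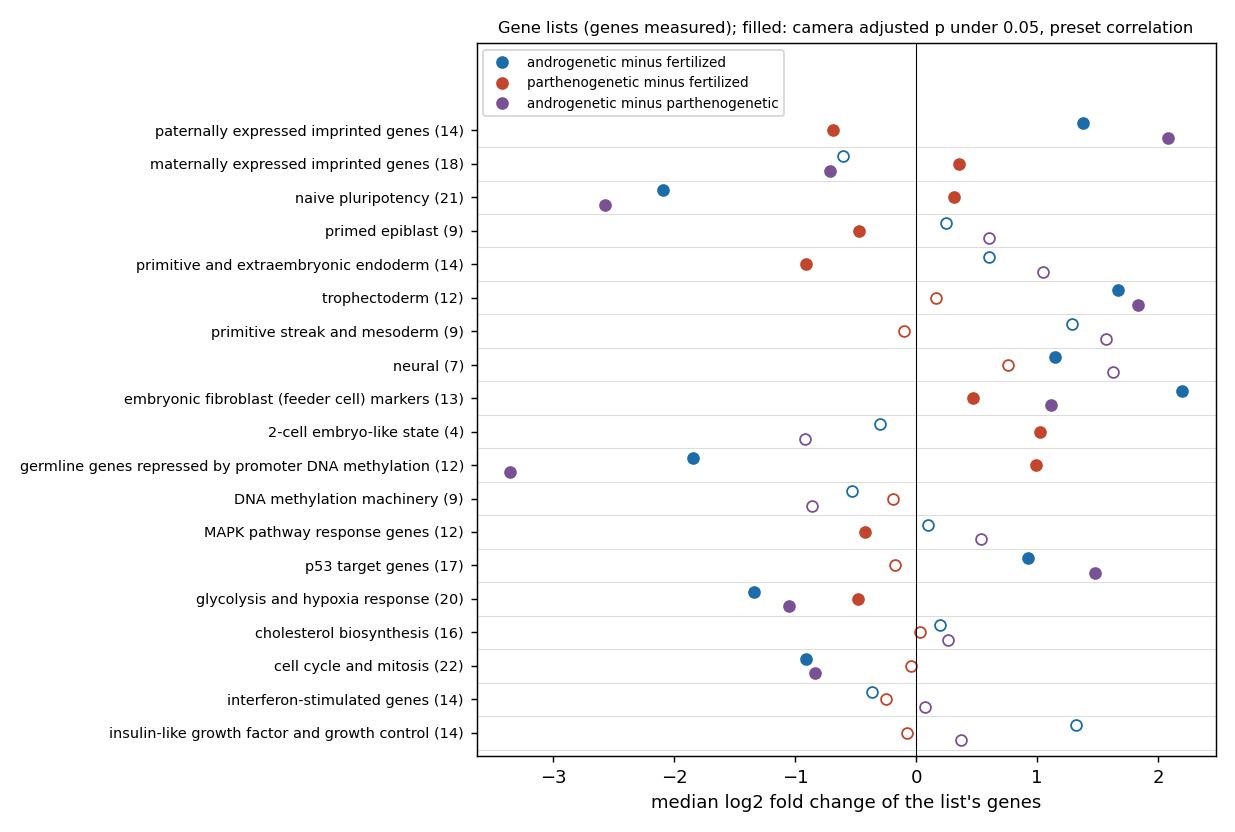
Median log2 fold change (x axis) of the measured genes of 19 lists (rows, number of genes measured in parentheses) in the 3 comparisons. Filled points passed camera's test at an adjusted p under 0.05 with a preset correlation, and none did with an estimated correlation. The naive pluripotency list lay at -2.09 in androgenetic and 0.31 in parthenogenetic cells, each against fertilized cells.

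Parthenogenetic cells were compared with fertilized cells to ask how expression differs when both genomes are maternal. Paternally expressed genes were lower. Snrpn, which encodes a splicing protein, was 12.8-fold lower (log2 fold change -3.68 ± 0.079 SE, adjusted p = 7.29e-08), yet still detected on both arrays at 10.06 ± 0.021 (log2 signal, SD, n = 2). Mest was 8.72-fold and Igf2 3.15-fold lower. Nnat and Peg3 were not detected in parthenogenetic cells and were at least 5.15-fold and at least 3.14-fold lower. A dimmer Nnat probe fell by 1.05 on the log2 scale (adjusted p = 0.000314). Of 14 measured genes 8 fell and 3 rose (median -0.68, or -0.60 with undetected genes at their bound; camera adjusted p = 0.0114; adjusted p = 0.170 with an estimated correlation). Over only the 11 genes detected on all 8 arrays the median was -0.12 and the list did not pass (camera adjusted p = 0.301), and it was -0.36 with no filter on dim probes and -0.46 with no background correction. Requiring detection on all 8 arrays removes genes not detected in parthenogenetic cells, Nnat and Peg3 among them. A weaker shift under that filter follows from the filter itself.

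Maternally expressed genes were modestly higher, with 10 of 18 up and 0 down (median 0.36, camera adjusted p = 0.000737; adjusted p = 0.102 with an estimated correlation). H13 was 2.53-fold, Pon2 1.98-fold and Cobl 1.64-fold higher, and Qpct, above background on 1 of 3 fertilized arrays, also rose (adjusted p = 0.000258). Cdkn1c rose by 0.71 ± 0.091 and Igf2r by 0.63 ± 0.090 (log2, SE). H13 and Pon2 were also higher in androgenetic than in fertilized cells, by 0.86 and 3.29 (log2), and Qpct rose there too. Cobl, Cdkn1c and Igf2r were lower there. In parthenogenetic cells fibroblast markers rose as well, 8 of 13 up and 1 down. Their median was 0.47 (camera adjusted p = 0.00897, or 0.162 with an estimated correlation). Both measured Y-linked genes were lower. Eif2s3y, a translation factor gene on the Y chromosome, was at least 17.6-fold lower and not detected. The Uty probe was 1.80-fold lower and still detected on both parthenogenetic arrays, at log2 signals of 6.65 and 7.04. Cells with maternal genomes alone have no Y chromosome, so that signal is not Uty transcript. The 1.80-fold is therefore a ratio of probe signals and not of Uty expression.

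X-linked genes were higher as a group. Over 278 genes the median log2 change was 0.62, with quartiles of 0.31 and 0.88, against -0.019 for the other genes. A total of 192 rose and 9 fell (camera adjusted p = 3.84e-22; adjusted p = 0.0311 with an estimated correlation). The labels do not give the number of X chromosomes per fertilized cell, so the X dose of the reference group may be mixed. Among the 19 autosomes the largest absolute median was 0.085, on chromosome 18. The X-linked gene Xlr4a was 67.2-fold higher (log2 fold change 6.07 ± 0.14 SE, adjusted p = 8.64e-08) and the X-linked homeobox gene Rhox9 rose by 3.17 ± 0.16 (log2, SE). Both belong to the list of germline genes silenced by promoter methylation, of which 10 of 12 rose and 0 fell (median 0.99, or 0.94 with undetected genes at their bound and 1.79 over the 4 detected on all 8 arrays; camera adjusted p = 5.82e-06; adjusted p = 0.102 with an estimated correlation). The 6 members at least 2-fold higher were all X-linked: Xlr4a, Rhox9, Rhox5, Rhox6, Taf7l and Tex11. The rise of this list therefore overlaps that of the chromosome.

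**Figure D3:**
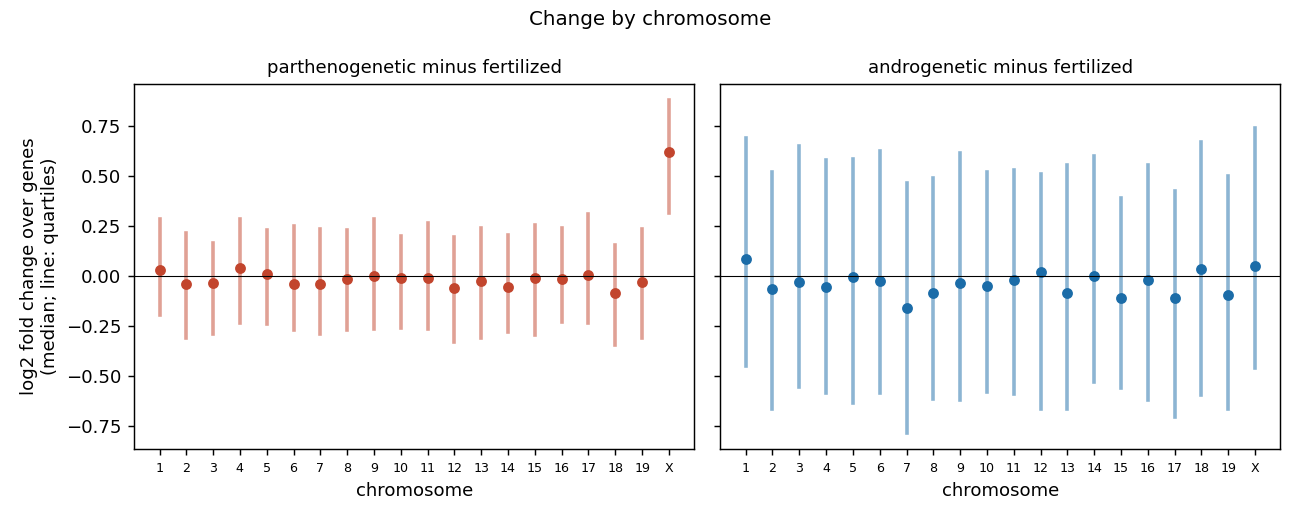
Log2 fold change against fertilized cells (y axis) of the named genes on each chromosome (x axis) in parthenogenetic (left) and androgenetic (right) cells. Points are medians over genes and lines run between the quartiles. The X chromosome lay at 0.62 in parthenogenetic and 0.049 in androgenetic cells.

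Naive pluripotency genes were slightly higher in parthenogenetic than in fertilized cells, with 13 of 21 up and 3 down (median 0.31, camera adjusted p = 0.0122; adjusted p = 0.103 with an estimated correlation). Zfp42 was 4.08-fold and Tcl1 3.11-fold higher. Nanog rose by 0.72 ± 0.14 (log2, SE), whereas Pou5f1 at 0.32 ± 0.10 and Sox2 at 0.31 ± 0.10 passed narrowly (adjusted p = 0.0374 and 0.0428) and lost the call when any 1 androgenetic array was left out. A dimmer Sox2 probe had a change of -0.28 (adjusted p = 0.301). Primitive endoderm genes were lower, with 10 of 14 down and 1 up (median -0.91, or -0.59 with undetected genes at their bound; camera adjusted p = 0.000374; adjusted p = 0.137 with an estimated correlation). Gata6, a regulator of that lineage, was at least 3.62-fold lower and Dab2 3.93-fold lower. Primed epiblast genes also fell, 6 of 9 (median -0.47, or -0.41 with undetected genes at their bound; camera adjusted p = 0.00133; adjusted p = 0.102 with an estimated correlation), Otx2 by 2.61-fold. Of 4 genes of the 2-cell-like state 3 rose (median 1.03, or 0.74 with undetected genes at their bound; camera adjusted p = 0.0122; adjusted p = 0.137 with an estimated correlation), Tcstv3 by at least 2.09-fold and Tcstv1 by at least 1.39-fold.

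MAPK response genes were lower in 7 and higher in 3 of 12 cases (median -0.43, camera adjusted p = 0.0278; adjusted p = 0.211 with an estimated correlation), and the immediate early genes Egr1 and Fos were 3.43-fold and 3.15-fold lower. Glycolysis and hypoxia genes fell in 12 and rose in 1 of 20 cases (median -0.48, camera adjusted p = 0.000525; adjusted p = 0.230 with an estimated correlation), Aldoc by 3.68-fold and Egln3 by 2.25-fold. The fibroblast markers were again higher, 8 of 13 up and 1 down (median 0.47, or 0.36 with undetected genes at their bound; camera adjusted p = 0.00897; adjusted p = 0.162 with an estimated correlation), and Col5a1 was 2.92-fold higher. The call of that list was lost over probes detected on all 8 arrays (camera adjusted p = 0.130). The neural list, with 4 of 7 up including Map2 (3.56-fold) and Stmn2 (2.64-fold), lay at its threshold (camera adjusted p = 0.0501).

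Other lists did not pass. Trophectoderm genes were split 5 up and 3 down of 12 (camera adjusted p = 0.443), Ets2 being 1.80-fold higher. Mesoderm genes were split 3 up and 2 down of 9 (camera adjusted p = 0.772), with Lefty2 2.36-fold and Gsc at least 1.13-fold higher. p53 targets were split 3 up and 6 down of 17 (camera adjusted p = 0.235), Pmaip1 being 1.74-fold lower. DNA methylation genes were split 2 up and 4 down of 9 (camera adjusted p = 0.390), Dnmt3l being 1.37-fold lower. Interferon genes were split 3 up and 5 down of 14 (camera adjusted p = 0.260), Oasl2 being 2.76-fold lower. Growth control genes were split 5 up and 4 down of 14 (camera adjusted p = 0.860), with Igfbp7 4.49-fold higher. Cholesterol genes were split 4 up and 3 down of 16 (camera adjusted p = 0.769), the X-linked Ebp being 3.58-fold higher. Cell cycle genes were split 3 up and 5 down of 22 (median -0.039, mean 0.0022, camera adjusted p = 0.852), Ccnd3 being 1.67-fold higher.

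Outside the lists the largest increases by fitted values were in Gbp2b (at least 9.60-fold), H2-Bl (at least 6.08-fold), Oas1g (8.09-fold) and Samd9l (at least 2.68-fold), and Cxcl12, a chemokine, was 8.98-fold lower. In total 3334 of 8221 genes differed at an adjusted p under 0.05 (limma), 1665 higher and 1669 lower, and 453 differed by at least 2-fold, 269 higher and 184 lower. Among the 1038 kept probes without a name, 91 were higher and 47 lower by at least 2-fold. Adjusted over the list alone, the counts up and down were 4 and 8 for paternally expressed, 0 and 8 for primed epiblast, 6 and 3 for trophectoderm, 3 and 3 for mesoderm, 5 and 2 for neural, 11 and 0 for germline, 3 and 7 for p53, 2 and 14 for glycolysis and 5 and 5 for growth control genes, and the same as above for the other lists. Without parthenogenetic replicate 1 the count was 2190, from a lone parthenogenetic array assumed to vary like the other arrays. The 2-fold count was 231 with neither background correction nor offset, and 245 with normexp correction and an offset of 50.

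Androgenetic and parthenogenetic cells were compared directly, paternal against maternal genomes. Paternally expressed imprinted genes were higher in androgenetic cells. Nnat was at least 56.0-fold higher in androgenetic cells, Mest 41.4-fold (log2 fold change 5.37 ± 0.15 SE, adjusted p = 1.75e-08), Igf2 12.3-fold, Peg10 at least 14.0-fold and Peg3 at least 13.1-fold higher. Snrpn had a log2 change of 3.91 ± 0.079 (SE). Of 14 paternally expressed genes 10 were higher and 1 lower (median 2.08, camera adjusted p = 0.000330; adjusted p = 0.102 with an estimated correlation). The median was 1.12 over the 11 genes detected on all 8 arrays, a filter that removes Nnat and Peg3, and 1.19 with no filter on dim probes. Fibroblast markers were higher in this comparison too, 12 of 13 (camera adjusted p = 0.000525; adjusted p = 0.102 with an estimated correlation). Grb10 was 83.0-fold lower (log2 fold change -6.38 ± 0.11 SE, adjusted p = 2.44e-09), Cdkn1c 14.5-fold, Igf2r 6.08-fold, Cobl at least 11.4-fold and Slc22a18 at least 4.47-fold lower. The Grb10 fold again rests on androgenetic signals just above the start of detection. Of 18 maternally expressed genes 12 were lower and 3 higher (median -0.71, or -0.52 with undetected genes at their bound; camera adjusted p = 0.0155; adjusted p = 0.162 with an estimated correlation). Eif2s3y was at least 16.4-fold and the Uty probe 1.53-fold higher in androgenetic cells, the latter against a parthenogenetic signal that is not Uty transcript.

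Pluripotency genes were lower in androgenetic than in parthenogenetic cells, in 19 of 21 cases (median -2.58, camera adjusted p = 3.71e-07; adjusted p = 0.0808 with an estimated correlation). Sox2 was 8.70-fold, Nanog 7.02-fold, Pou5f1 5.96-fold and Tcl1 35.1-fold lower, and Fgf4 at least 11.5-fold lower. All 12 germline genes were lower (median -3.36, or -2.36 with undetected genes at their bound; camera adjusted p = 7.80e-06; adjusted p = 0.102 with an estimated correlation), Xlr4a by at least 95.9-fold and Rhox9 by 37.4-fold. Trophectoderm genes were higher in 9 and lower in 2 of 12 cases (median 1.84, camera adjusted p = 0.00307; adjusted p = 0.137 with an estimated correlation), Eomes by at least 5.17-fold and the keratin gene Krt18 by 5.67-fold. p53 targets were higher in 15 and lower in 2 of 17 cases (median 1.48, or 1.38 with undetected genes at their bound; camera adjusted p = 0.000360; adjusted p = 0.102 with an estimated correlation), Fas by at least 7.02-fold; Plk2 had a log2 change of 2.91 ± 0.088 (SE). Cell cycle genes were lower in 18 of 22 cases (median -0.83, camera adjusted p = 0.00178; adjusted p = 0.137 with an estimated correlation), Bub1b by 2.74-fold, with Ccnd2 2.97-fold higher. Glycolysis genes were lower in 15 of 20 cases (median -1.05, camera adjusted p = 0.00603; adjusted p = 0.336 with an estimated correlation), Pfkp by 8.13-fold and Pdk1 by 4.88-fold. Fibroblast markers were higher in 12 and lower in 1 of 13 cases (median 1.11, camera adjusted p = 0.000525; adjusted p = 0.102 with an estimated correlation), Thbs1 by 4.13-fold and Timp3 by 4.01-fold.

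The lists that did not pass in this comparison were primitive endoderm (camera adjusted p = 0.0779; Foxq1 at least 12.4-fold and Gata6 at least 6.97-fold higher), mesoderm (0.0564; Msx1 at least 17.2-fold and Gsc 5.88-fold higher) and neural genes (0.0903; Gap43 9.63-fold higher). Primed epiblast genes had an adjusted p of 0.276 (Otx2 8.19-fold lower), 2-cell genes 0.0893 (Zscan4c at least 6.29-fold lower), DNA methylation genes 0.180 (Dnmt3l 12.6-fold lower) and MAPK genes 0.148 (Fos 5.36-fold higher, Klhl13 4.59-fold lower). Cholesterol genes had an adjusted p of 0.402 (Hsd17b7 4.63-fold higher), interferon genes 0.465 (Isg15 at least 4.86-fold higher) and growth control genes 0.726. Among the largest differences outside the lists were Sp5 (67.3-fold higher), Tmprss2 (at least 24.4-fold higher), Gstp2 (at least 107-fold lower), Fthl17f (at least 19.2-fold lower) and Gpx2 (at least 25.9-fold lower). Smc1b, which encodes a meiotic cohesin, was also lower and not detected in androgenetic cells (adjusted p = 1.58e-09). X-linked genes had a median of -0.48 (camera adjusted p = 0.00517; adjusted p = 0.967 with an estimated correlation), and in androgenetic against fertilized cells they had a median of 0.049 (camera adjusted p = 0.991). In total 5845 of 8221 genes differed at an adjusted p under 0.05 (limma), 2792 higher and 3053 lower in androgenetic cells, and 2242 by at least 2-fold, 1042 higher and 1200 lower. The 1038 kept probes without a name leaned the other way, with 337 higher and 171 lower by at least 2-fold. Adjusted over the list alone, primitive endoderm counts were 9 up and 5 down in place of 8 and 4, and those of the other lists were the same. Over probes detected on all 8 arrays the 2-fold count was 1460 and the median of p53 targets 0.81, and with no background correction the median of germline genes was -2.20.

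The comparisons against fertilized cells were then set against each other. In both uniparental kinds 813 genes were higher and 961 lower than in fertilized cells, among them Gbp2b and Col5a1 on the higher side and Otx2, Pdk1 and Egln3 on the lower. Another 385 genes were higher in androgenetic and lower in parthenogenetic cells, including Igf2, Nnat, Mest and Peg3, and 541 were lower in androgenetic and higher in parthenogenetic cells, including Cdkn1c, Igf2r, Nanog and Rhox9. Independent lists of these sizes would share 589 higher and 656 lower genes and hold 590 and 655 in the opposite classes. Unchanged groups simulated against shared controls gave 0 in each class, a count that holds no effects and so does not size the part of the controls. The covariance of the log2 changes was 0.119, against 0.00706 in simulated unchanged groups, and their correlation across genes was 0.21, against 0.45. With the fertilized arrays divided, 1 for 1 comparison and 2 for the other, the 6 divisions gave 522 to 815 genes higher and 565 to 952 lower in both, 217 to 455 and 363 to 650 in the opposite classes, where independent lists would hold 366 to 645, 354 to 677, 318 to 629 and 407 to 727. In each division the counts in the same direction lay above those of independent lists and the opposite counts below, with a covariance of 0.0883 to 0.115. No division leaves 2 arrays on each side, so part of the excess in the undivided counts may come from the shared controls. The fertilized arrays may also be passages of the same line. Expression peculiar to that line would then enter both comparisons in each division too. Without parthenogenetic replicate 1 the first 3 undivided counts were 539, 640 and 251.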

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

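The stricter threshold for total counts, and the fits without each array for chromosomes and for the overlap, and the division of the fertilized arrays were chosen only after the result was seen. Of 159 named gene results 155 kept their call and direction under each alternative run. Snrpn (androgenetic against fertilized), Pou5f1 and Sox2 (parthenogenetic against fertilized) and Uty (androgenetic against parthenogenetic) lost the call under at least 1, and none changed direction. Genes at least 2-fold different in parthenogenetic against fertilized cells numbered 231 with no background correction or offset, 245 with normexp at offset 50, 240 with the authors' values and 230 over probes detected on all 8 arrays. That last filter, which left 6601 genes, gave 1507 for androgenetic against fertilized and 1460 for androgenetic against parthenogenetic cells. With no 2-fold minimum the counts were 6140, 3334 and 5845, and at an adjusted p under 0.01 the total for parthenogenetic against fertilized cells was 2102. The replicate block gave 6065, 2896 and 5609 genes, 2321, 448 and 2237 of them at least 2-fold. With each array left out in turn, the total for parthenogenetic against fertilized cells was 2190 to 3621, genes higher in both uniparental kinds 539 to 911, lower in both 640 to 1076, and higher in androgenetic and lower in parthenogenetic cells 251 to 440, each lowest without parthenogenetic replicate 1. With the fertilized arrays divided, fertilized replicate 1 for parthenogenetic cells alone, the same 3 classes held 522, 565 and 217 genes, with the lone array assumed to vary like the others. Fits without an array kept the probes chosen on 8 arrays. The 28 list calls held under each setting but 2. Lists without a call gained one in the same direction 14 times under camera: neural genes in parthenogenetic against fertilized cells under 10 settings, and mesoderm and primitive endoderm genes in androgenetic against parthenogenetic cells under 3 and 1. Over probes detected on all 8 arrays, a filter that drops genes not detected in 1 group, 25 held. Paternally expressed genes in parthenogenetic against fertilized cells had a median of -0.12 (adjusted p = 0.301), fibroblast markers there lost the call, and 2-cell genes had too few members. Fits of 2 groups adjusted list p-values within 1 comparison. Camera with an estimated correlation has only the 5 residual degrees of freedom. In androgenetic against fertilized cells its p-values rose even for naive pluripotency (estimate -0.032) and p53 targets (0.0065), both below the preset 0.01. With an estimated correlation none of the 28 passed. The medians were then unchanged at 1.38, -0.68 and 2.08 for paternally expressed genes in the 3 comparisons (adjusted p = 0.102, 0.170 and 0.102), 0.36 and -0.71 for maternally expressed genes in parthenogenetic against fertilized and androgenetic against parthenogenetic cells (0.102 and 0.162), and -0.48 for the X chromosome in the latter (0.967). Fry tests a list against no change, not against other genes, and so passes readily where many genes differ: 55 of 57 list results passed, 25 of them new calls in the same direction. Under fry, maternally expressed genes passed in androgenetic against fertilized cells (median -0.60, adjusted p = 6.25e-07). Fry also turned the direction of primed epiblast genes (median 0.24, down, adjusted p = 0.0163), interferon genes (median -0.36, up, adjusted p = 0.00209) in that comparison, and of cell cycle genes in parthenogenetic against fertilized cells (median -0.039, up, adjusted p = 0.961). In all, 50 directions of lists or chromosomes turned, 48 of them with neither value past the threshold. Direction is that of the test, which weighs genes by their spread and can differ from the sign of the median. The medians there follow. With no background correction, chromosome 19 -0.043 (androgenetic against parthenogenetic). With normexp with offset 50, chromosome 19 -0.043 (androgenetic against parthenogenetic). With median scaling, chromosome 10 -0.10, chromosome 11 -0.069 (androgenetic against fertilized) and chromosome 16 -0.072, chromosome 8 -0.048 (androgenetic against parthenogenetic). With the authors' values, chromosome 10 -0.026 (androgenetic against fertilized) and chromosome 19 -0.025 (androgenetic against parthenogenetic). With no filter on dim probes, chromosome 11 -0.035 (androgenetic against fertilized) and chromosome 5 0.011 (parthenogenetic against fertilized) and chromosome 10 -0.047, chromosome 19 -0.046 (androgenetic against parthenogenetic). Over probes detected on all 8 arrays, primed epiblast -0.060, MAPK pathway response genes 0.011, chromosome 6 -0.045 (androgenetic against fertilized) and insulin-like growth factor and growth control -0.075, chromosome 10 -0.0030, chromosome 17 -0.020, chromosome 9 -0.012 (parthenogenetic against fertilized) and chromosome 19 -0.046 (androgenetic against parthenogenetic). With a replicate block, cell cycle and mitosis -0.0017 (parthenogenetic against fertilized). With each array left out in turn, medians in androgenetic against fertilized cells ranged over chromosome 11 -0.035 to -0.022, chromosome 10 -0.059 to -0.034. In parthenogenetic against fertilized cells they ranged over chromosome 9 -0.019 to 0.0039, chromosome 5 -0.0059 to 0.016, cell cycle and mitosis -0.095 to 0.030, chromosome 16 -0.025 to -0.0076, chromosome 17 -0.035 to 0.034. In androgenetic against parthenogenetic cells they ranged over chromosome 16 -0.11 to -0.038, chromosome 10 -0.086 to -0.023, chromosome 11 -0.051 to -0.027, chromosome 19 -0.055 to -0.0031, chromosome 13 -0.078 to -0.036. The slide block was not run, since the column names give no slide.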

Other observations

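Naming the genes opposite in the 2 uniparental kinds, and all tests in this part except the blocks of the X chromosome and the other splits of the arrays, were chosen only after the result was seen. Among genes at least 2-fold different from fertilized cells in both kinds, 83 were higher in both and 92 lower in both. Another 19 were higher in androgenetic and lower in parthenogenetic cells. They included 6 of the paternally expressed list, Nnat, Mest, Peg3, Igf2, Impact and Peg10, more than among other genes (Fisher exact p = 1.88e-13, genes taken as independent). With undetected genes at their bound the classes were 51, 80 and 13 genes, 5 of the 13 from that list. The others included Dab2 (1.01 and -1.97, log2 against fertilized in androgenetic and parthenogenetic cells), Bcl6 (1.74 and -1.90) and the WNT target Axin2 (2.74 and -1.09). In the opposite class were 63 genes (41 at the bounds), 0 of the 63 from the maternally expressed list (Fisher exact p = 1). The 2-fold minimum settled that 0, so the test does not decide. Only 1 of 18 measured members, H13, rose at least 2-fold in parthenogenetic cells, and it rose in androgenetic cells too. With no 2-fold minimum, Cdkn1c, Igf2r, Cobl and Slc22a18 were lower in androgenetic and higher in parthenogenetic cells. The 63 genes included the pluripotency genes Klf4 (-1.40 and 1.22), Nr5a2 (-1.10 and 1.44) and Tcl1 (-3.49 and 1.64), and the X-linked Rhox5 (-2.35 and 2.83).

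The X-linked multicopy families Rhox, Xlr, Mage and Fthl were higher in parthenogenetic than in fertilized cells, in 9 of 9 measured genes, from Maged1 (log2 change 0.37) to Xlr4a (6.07). X-linked genes in general were higher there (192 of 278, median 0.62), so part of this is common to the chromosome. In androgenetic cells they went both ways. Rhox9 was at -2.06 there, against 3.17 in parthenogenetic cells, whereas Maged2 and Magee1 were at 2.13 and 2.40 in androgenetic cells.

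Naive pluripotency genes were lower in androgenetic than in fertilized cells. Dilution by fibroblast RNA would lower markers that fibroblasts lack by a common amount. The changes of 21 genes had an SD of 1.49 (1.33 with undetected genes at their bound) around a median SE of 0.094 and ran up to 0.60. Which of the 21 genes fibroblasts express was not measured. Members that they express would spread the changes under dilution too, so this spread does not decide. Fibroblast markers were themselves higher, with Acta2 at a mean log2 signal of 15.50 against 13.98 in fertilized cells and Col1a1 at 8.35 against no detection, although 11 of the 13 were also detected on fertilized arrays and the labels name no sort, so a share of fibroblast RNA stays open. The choice of background correction, or of quantile or median scaling, is argued against as the whole cause, since over the 4 others the list's median nearest 0 was -2.05. Among the 4, no background correction and the authors' values are nearly the same processing. All 4 equalise the arrays, so that step itself was not tested. A state of the lines sampled, or differentiated cells in them, cannot be told apart from androgenesis, because androgenetic arrays correlated at 0.997 or more and may be passages of the same line.

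X-linked genes were higher in parthenogenetic than in fertilized cells. The largest median change of an autosome was 0.085, on chromosome 18, which argues against normalization or array brightness. The multicopy families hold 9 genes, whereas 192 of 278 X-linked genes were higher, which argues against these families as the whole cause. Without the 9 genes the X median was 0.59, but dropping so few of 278 could hardly move a median. A higher dose of the whole chromosome may account for it, as a hypothesis, since 10 of 10 blocks of neighbouring genes had a median above 0.2, from 0.43 to 0.72, and the brightest of 3 classes of X-linked genes had a median of 0.63. The number of active X chromosomes per cell was not measured, and the fertilized samples, labelled female and male, may mix X doses.

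Paternally expressed imprinted genes were higher in androgenetic than in fertilized cells. The list's mean change of 1.44 lay at percentile 100 of 10000 random lists matched on expression, whose middle 95% ran from -0.58 to 0.50, but such lists ignore correlation between members, and with an estimated correlation the list did not pass (adjusted p = 0.102), so broad differences between the lines stay open. The rule that each measured gene doubles, as exactly 2 active copies in place of 1 would give with nothing else changed, is argued against. Only 2 of 14 members had a 95% interval that held a log2 change of 1, with 8 above and 4 below. These intervals measure spread between passages, and imprinting of each member in these cells was not measured. The number of active copies itself therefore stays open. Parental origin of the genomes stays open with the state of the lines sampled and with fibroblast RNA, which may add to single genes, as fibroblast markers were higher in the same comparison (median 2.20, camera adjusted p = 0.000330; adjusted p = 0.102 with an estimated correlation). For the count of genes differing in androgenetic against fertilized cells, the 10 splits of the 6 arrays are too few for a share under 0.05, with 6044 genes in the real split, 1 split with as many (the real one), and 0 in the highest other.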
